A study of Drosophila melanogaster with 3 samples.

How the data were processed

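Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of mixed sex, aged 0 to 24 hours, from a transgenic line that carries CG4617 with GFP fused to its C terminus, per the labels. The antibody was raised against GFP, and chromatin was sheared by sonication to fragments of 200 to 800 bp. There were 3 biological replicates with 1 technical replicate each, all in 1 group, CG4617-eGFP anti-GFP ChIP. The labels describe the replicates as separate biosamples. No control group is among the samples, so no comparison between groups was made.

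The deposited files are lists of genomic regions with a signal value per region. Per the labels' listing text, each replicate has a list of peaks and background regions meant as input for the irreproducible discovery rate procedure (IDR), made from the alignments of that library and 1 control alignment. A pooled list came from all 3 libraries and the control, and a thresholded list was derived by IDR from the replicate and pooled lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal of each region is the authors' own deposited value, on a scale that is not stated, and it was used to rank regions within a list, for rank and log2 correlations between replicate lists and for medians within the thresholded list. Reads per library are not given in the files analysed here, so depth is unknown. All lists exist for the builds dm6 and dm3, and coordinates below are in dm6, counted from 1.

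The dm6 thresholded list was read as the set of peaks, with 5558 entries. Each of them is also in the pooled list, with the same interval and signal, and they are the 5558 highest signals there. Peaks had a median width of 440 bp, and 628 neighbouring pairs overlapped, so peaks are not fully independent. The summit was the deposited summit position, which lay at the middle of the region in 71.8% of peaks and outside the region in 3.

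Genes and transcription start sites (TSSs) were taken from Ensembl release 115 on the chromosome arms 2L, 2R, 3L, 3R, 4, X and Y, with transposable elements left out. This gave 13968 protein-coding genes with 19275 TSS positions. Sequence came from the RefSeq copy of the Release 6 genome, and no dm6 region lay beyond the arm lengths. A promoter peak is a peak with its summit within 500 bp of a protein-coding TSS. A gene was counted as having a promoter peak when any of its own TSSs lay within 500 bp of a summit.

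Replicate lists were compared through the share of thresholded summits inside a region of all 3 replicates, once with whole lists and once with the 5558 strongest regions of each. Chance was taken from 1000 circular shifts within arms (200 for alternatives), which keep the spacing of regions but also move them into heterochromatin. Promoter and annotation-class shares used the same kind of shift with a two-sided permutation p. Arm shares were tested with exact binomial tests against the share of protein-coding TSSs. Gene lists, divergent promoters and core promoter motifs (at the most upstream TSS of each gene, from 100 bp upstream to 50 bp downstream) were tested with two-sided Fisher exact tests, and odds ratios have 95% intervals. Motifs and 6-mers within 100 bp of summits were set against a window of equal width 500 bp to one side with exact McNemar tests. Each family was adjusted by the Benjamini-Hochberg method at 0.05. The trend of promoter share over 5 signal bins used 100000 permutations. Shares of single lists have Wilson intervals (exact ones for arms), which cover counting error only. The list, divergent promoter and motif tests treat genes and peaks as independent, although neighbouring genes can share a peak.

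Groups, tests, alternatives, 25 gene lists and 18 motifs, 9 of them core promoter motifs, were chosen before the data were examined. The gene lists are named with their results. For 4 lists some names had no match in the annotation: 33 of 35 were found for the spliceosome, 29 of 31 for Polycomb and Trithorax proteins, 19 of 21 for insulator proteins and 33 of 34 for segmentation genes. The genes named are those at the 20 peaks with the highest signal, taking the nearest TSS within 500 bp, otherwise the host gene, otherwise the nearest TSS. For each list past the threshold they are the 3 members with the strongest promoter peak, for lists with fewer peaks up to 3 that have one, for every other list 2 members, and CG4617. Some other genes with a TSS within 500 bp of the same summit are given beside them. Genes named for any other reason are marked as chosen after their values were seen.

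Alternatives were the genome build, the overlap that counts as shared, promoter windows of 250 and 1000 bp, the stronger 2779 peaks, 1 TSS per gene, other motif windows, subsets of peaks, and leaving out each replicate in turn. The thresholded list cannot be remade without a replicate. For gene lists, peaks were therefore kept only where the summit lay among the 5558 strongest regions of all 3 replicates, or of the other 2 when a replicate was left out. This support filter is stricter than the thresholded list and lowers the number of genes with a peak, so a change under it cannot be put down to the replicate left out alone. Alternatives chosen after seeing the data were merging of overlapping peaks, a corrected chorion list and gene lists without divergent genes. The tests were also tested on simulated data. With 80% of 3000 summits placed at promoters, the promoter share came out at 82.4%. With 5 of 25 lists of 30 genes set to a share of 70% against 37%, the list test recovered 82.8% of the changed lists and called 0.7% of the others. A 6-mer planted in 10% of windows was recovered among 2080 6-mers with 3 calls, and 0 were called with nothing planted. The simulated genes did not share peaks, and the simulated windows lay at random places. Real summits had 39.8% G and C bases against 44.3% in flanks, so these rates of false calls need not hold for the data. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.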

Results

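Binding of the CG4617-GFP fusion protein along the fly genome was described from 3 replicate ChIP-seq region lists and the thresholded list that the authors derived from them. The thresholded list held 5558 peaks covering 2.00 Mb. Replicate 1 listed 30000 regions, replicate 2 17251 and replicate 3 14368, covering 11.9, 6.66 and 5.41 Mb. These lists include background regions, so their lengths do not measure binding. Depth in reads is unknown, and the signal values printed here are the authors' own.

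The replicates marked the same places far beyond chance. Of the 5558 thresholded summits, 87.5% lay inside a region of all 3 replicate lists, against a mean of 0.0172% over 1000 circular shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Replicates 1, 2 and 3 held 97.8%, 98.7% and 90.5% of the summits. The thresholded list was made from these same lists, so the overlap describes them and is no independent check. With each replicate kept to its 5558 strongest regions, 61.4% of summits (3410 peaks) were held by all 3, 1730 peaks by 2 replicates, 407 by 1 and 11 by 0. Across peaks, which are not independent replicates, the Spearman correlation of signal was 0.611 between replicates 1 and 2, 0.561 between 2 and 3 and 0.406 between 1 and 3 (Pearson 0.609, 0.607 and 0.433 on log2 signal). Their mean was 0.526 ± 0.107 (SD, 3 pairs).

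The highest signal, 2038, was at the promoter of CG14100 on 3L, in a peak from 19590423 to 19590826 whose summit lay 88 bp from the TSS, and this region ranked first in all 3 replicates. The 61 bp around that summit, 19590582 to 19590642, read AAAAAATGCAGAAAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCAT. The second peak, with signal 1816, lay 35 bp from the TSS of Ugalt, a UDP-galactose transporter gene on X, and ranked 2, 2 and 3 in the replicates. The third, with signal 1630 on 2L at 481057, lay in an intron of ush, which encodes a zinc-finger cofactor of GATA factors. Among the 20 strongest peaks, 14 were at promoters, 5 in introns and 1 between genes. The other promoter peaks were at Art3 with mRpS10, px, Chro with Ssl1, mRpL41, PNPase, Tcs5 with CHMP2B, CG1888, CenG1A with mRpS23, ph-p, tank with CG12194, CG8320 with Pex11ab, and Shc with Atat, in falling order of signal from 1450 to 1062. The other intronic ones were in CG11050 (signal 1321), Lk6 (1185), HmgD (1165) and CG32772 (1060), and the intergenic one (1401) lay 11927 bp from its nearest TSS, that of CG13323.

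Most peaks sat on promoters. The summit lay within 500 bp of a protein-coding TSS in 4532 of the 5558 peaks, 81.5% (95% interval 80.5 to 82.5), against 11.5% expected from shifts (two-sided permutation p = 0.002, the smallest these shifts can give). The median distance to a TSS was 101 bp. Introns held 661 peaks, 11.9% against 39.8% expected, and the space between genes held 288, 5.18% against 27.9%. Coding exons held 7 peaks, 0.126% against 13.9% expected, 3' UTRs held 12, 5' UTRs outside the promoter window 14 and other parts of genes 44. All 7 shares differed from chance (permutation, adjusted p = 0.002 each, again the smallest). Each summit counts in 1 class only, so the high promoter share by itself lowers the shares of the other classes. Their low shares are therefore not separate evidence that peaks avoid those parts. Introns held 661 of the 1026 peaks outside promoters, and whether that differs from chance among such peaks was not tested. When gene parts were given priority over the promoter, the promoter class held 24.9% of summits, 5' UTRs 39.2%, above the chance share, coding exons 5.69% and introns 23.0%, and other parts of genes no longer differed from chance (permutation, adjusted p = 0.358). The promoter share of the strongest 5558 regions was 86.7% in replicate 1, 80.8% in replicate 2 and 69.4% in replicate 3, a mean of 79.0% ± 8.79 (SD, n = 3).

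Strong peaks lay at promoters more often than weak ones. In 5 bins of falling signal, the promoter share was 89.5%, 88.1%, 82.1%, 76.7% and 71.3% (two-sided permutation p = 1e-05, the smallest 100000 permutations can give). The difference between the first and the last bin was 18.2 percentage points. It was 17.6 points in replicate 1, 18.6 in replicate 2 and 29.4 in replicate 3, whose weakest bin had 52.3% at promoters.

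**Figure D1:**
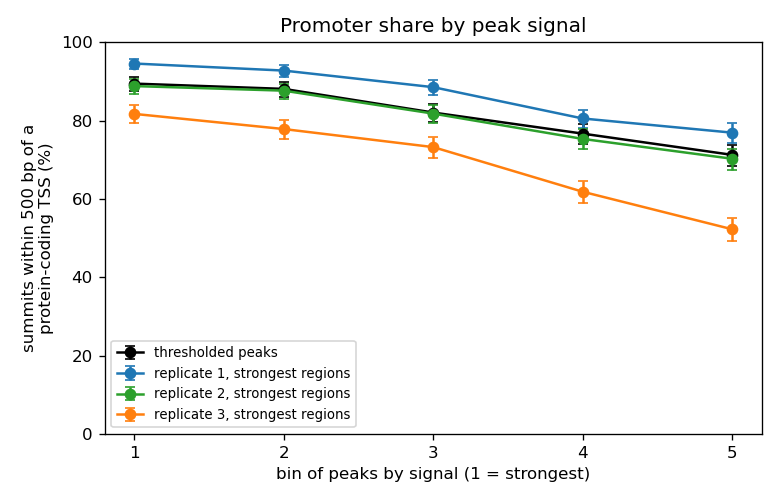
Share of summits within 500 bp of a protein-coding TSS (y axis, %) in 5 bins of peaks ranked by signal (x axis, 1 the strongest), for the thresholded peaks and for the 5558 strongest regions of each replicate; bars are 95% Wilson intervals. The thresholded peaks go from 89.5% to 71.3%, and replicate 3 lies lowest in each bin.

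Chromosome 4 had more peaks and the Y chromosome fewer than their share of TSSs. Chromosome 4 held 60 peaks, 1.08% of all, 1.47 times its share of TSSs (exact binomial test, adjusted p = 0.0161), and the Y chromosome held 0, against 0.119% of TSSs (exact interval up to 0.0663%, adjusted p = 0.0161). The X held 888 peaks, 15.98% against 17.0% of TSSs, a ratio of 0.940 that missed the threshold (exact binomial, adjusted p = 0.0796). Among the stronger 2779 peaks the X ratio was 0.794 (exact binomial, adjusted p = 3.41e-06), and among promoter peaks 0.873 (adjusted p = 0.000626). The embryos were of mixed sex and the number of X copies was not taken into account, so these ratios do not measure binding per copy. With sequence length as reference the chromosome 4 ratio was 1.10 (exact binomial, adjusted p = 0.529), and among the stronger 2779 peaks it was 1.56 (adjusted p = 0.0505), where the Y call was lost too (adjusted p = 0.123). The Y is rich in repeats, and how reads with several matches were treated is not given in the sources used here, so 0 listed peaks there does not show a lack of binding.

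A promoter peak was found at 5179 of 13968 protein-coding genes, 37.1% (replicates 35.9% ± 2.04, SD, n = 3). Genes of protein synthesis, energy metabolism, RNA processing and chromatin had one far more often. Cytoplasmic ribosomal protein genes had a peak at 74 of 85 members (odds ratio 11.6, adjusted exact p = 5.88e-21), with RpL7 (signal 926), RpL34b (768) and RpS27 (766) the strongest. Mitochondrial ribosomal proteins had one at 56 of 73 (odds ratio 5.64, adjusted exact p = 2.53e-11), led by mRpS10 (1450), mRpL41 (1255) and mRpS23 (1180). Translation factors had 36 of 51 (odds ratio 4.09, adjusted exact p = 2.54e-06), led by eIF6 (998), eIF4G2 (596) and eIF4EHP (531), and aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 27 of 33 (odds ratio 7.67, adjusted p = 4.01e-07), led by GluProRS, GlnRS and SerRS. The proteasome had 27 of 32 (odds ratio 9.21, adjusted exact p = 1.24e-07), led by Rpt5, Prosbeta1 and Rpt2. Oxidative phosphorylation had 59 of 84 (odds ratio 4.04, adjusted exact p = 2.39e-09), led by ATPsynF (792), ATPsynB and COX6B, and the spliceosome 30 of 33 (odds ratio 17.1, adjusted p = 5.08e-10), led by Prp3, Sf3a1 and Prp18. Keeping only peaks with the summit among the strongest regions of all 3 replicates left 3707 genes with a peak and odds ratios of 5.41 for cytoplasmic and 3.57 for mitochondrial ribosomal proteins, 6.12 for the proteasome, 3.33 for synthetases, 4.28 for the spliceosome and 2.67 for translation factors, all still past the threshold. With that filter on 2 replicates, leaving out replicate 1, 2 or 3, 3985, 3937 and 4484 genes kept a peak and the odds ratios were 7.27, 5.54 and 7.44 for cytoplasmic ribosomal proteins, 4.40, 4.48 and 4.25 for synthetases, 3.87, 4.48 and 21.3 for the spliceosome and 2.62, 2.46 and 4.25 for translation factors. Among the stronger 2779 peaks they were 3.88 for cytoplasmic and 2.86 for mitochondrial ribosomal proteins, 5.45 for the proteasome, 5.03 for the spliceosome and 1.86 for synthetases, and within 1000 bp 24.1 for cytoplasmic ribosomal proteins.

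Insulator and architectural proteins, which organise chromatin loops and domain borders, had the highest share, 18 of 19 genes (odds ratio 30.6, interval 4.09 to 230, adjusted exact p = 4.43e-07). Their strongest peaks were at Chro (1333), Cp190 (700) and CTCF (479). Polycomb and Trithorax genes, which keep developmental genes silent or active, had 24 of 29 (odds ratio 8.18, adjusted exact p = 1.13e-06), led by ph-p (1132), brm (721) and Jarid2 (575). Within 1000 bp the odds ratio was 20.1 for Polycomb and Trithorax genes (27 of 29) and 58.0 for the insulator list (19 of 19). Cell cycle and DNA replication genes had 30 of 43 (odds ratio 3.93, adjusted exact p = 3.27e-05), led by Dp (591), Psf1 (471) and dpa (408). Under the support filter the cell cycle list had 18 of 43 with all 3 replicates (Fisher's exact test, adjusted p = 0.0475) and also 18 without replicate 2, where it missed the threshold (adjusted p = 0.0717). It also missed the threshold among the stronger 2779 peaks (odds ratio 1.93, Fisher's exact test, adjusted p = 0.0634), as did the synthetase list (odds ratio 1.86, 0.117). The odds ratio of the insulator list under that filter was 14.8 with all 3 replicates and 13.4, 13.6 and 18.0 without replicates 1, 2 and 3, and 12.3 among the stronger peaks, and that of the cell cycle list was 2.00, and 2.18 and 1.84 without replicates 1 and 2. Many of these peaks lie at a start region shared with a neighbour, such as RpL7 with Ripalpha, Dp with Fsn or Chro with Ssl1, and are counted for both genes.

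Segmentation, dorsoventral, muscle, Hox, cuticle, antimicrobial peptide and chemoreceptor genes had promoter peaks less often than other genes, while the Notch pathway and neuronal lists did not pass the test. The chromatin came from whole embryos of mixed ages, so binding limited to few cells or a short stage could be missed. Which of these genes are active in the embryos was not examined, so low shares do not show that the protein avoids them. Segmentation genes had 2 of 33 (odds ratio 0.109, adjusted exact p = 0.000124), bcd (signal 234) and ptc (158), and under the support filter 1 of 33 with all 3 replicates (odds ratio 0.0863) or without replicate 3 (0.0659). Dorsoventral and mesoderm genes had 4 of 30 (odds ratio 0.261, adjusted exact p = 0.0088), among them tin (231), stumps (211) and Mef2 (201). Over the alternatives the odds ratio of that list ran from 0.0702 within 250 bp to 0.451 within 1000 bp. Muscle structural genes also had 4 of 30 (odds ratio 0.261, adjusted exact p = 0.0088), among them Msp300 (489), Tm1 (312) and sls (303). Hox genes had 0 of 8 (adjusted exact p = 0.0338). Cuticle proteins had 0 of 122 (adjusted exact p = 1.49e-24), antimicrobial peptides 0 of 20 (adjusted p = 0.00016) and chemoreceptors 4 of 179 (odds ratio 0.0380, adjusted p = 4.16e-29), with Ir60e, Gr63a and Ir60b sharing their peaks with CG13585, Lamtor4 and Letm1. The Hox list, at 0 of 8 in each of the following, lost its Fisher exact call under the support filter with all 3 replicates (adjusted p = 0.136) and without replicates 1, 2 and 3 (0.125, 0.126 and 0.0666), within 250 bp (0.0675), with 1 TSS per gene (0.0649) and among the stronger 2779 peaks (0.240), and kept it in 1 of 8 alternatives. Under that filter the exact call was also lost for muscle genes with all 3 replicates (adjusted p = 0.157) and without replicate 1 (0.0792) or 2 (0.115), and for dorsoventral genes without replicate 1 (0.0792), and otherwise for muscle genes among the stronger peaks (0.303) and dorsoventral genes within 1000 bp (0.0721).

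The chorion, vitelline and yolk list had 2 of 19 (odds ratio 0.199, adjusted exact p = 0.0193), but both members with a peak, Cp190 and Cp110, were caught by the name pattern and are not eggshell genes. Without them the list had 0 of 17 (odds ratio 0.0484, adjusted exact p = 0.000728), a correction chosen after seeing the data. The call of the full list was lost under the support filter without replicate 3 (odds ratio 0.248, Fisher's exact test, adjusted p = 0.0553) and among the stronger 2779 peaks (odds ratio 0.181, 0.0768). Against the share of protein-coding genes, tRNA genes had a peak within 500 bp at 7 of 290 (adjusted exact p = 7.31e-45), led by tRNA:Trp-CCA-2-2, tRNA:Tyr-GTA-1-8 and tRNA:His-GTG-1-3. These tRNA genes share their peaks with CG30122, CG8036 and CG8490. Small nuclear RNA genes had one at 2 of 32 (adjusted exact p = 0.000188), snRNA:U6:96Ab and snRNA:U6:96Ac at a single peak. Small nucleolar RNA genes had one at 14 of 269 (adjusted exact p = 2.1e-33), led by snoRNA:Or-aca5, snoRNA:Psi28S-2949 and snoRNA:Or-CD11a. Of these, snoRNA:Or-aca5 and snoRNA:Psi28S-2949 lie at a single peak, and snoRNA:Or-CD11a shares its peak with RpL28 and eIF1. Within 1000 bp the counts were 55 for small nucleolar RNA genes (odds ratio 0.381), 21 for tRNA genes (0.116) and 4 for small nuclear RNA genes (0.212), still lower than at protein-coding genes. Replication-dependent histones had 0 of 111 (adjusted exact p = 3.32e-22). Histone, tRNA and snRNA genes are repeated in the genome, and how the authors treated reads with several matches is not given in the sources used here.

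For 3 lists the share was not separable from that of other genes. Heat shock genes had 11 of 29 (odds ratio 1.04, interval 0.489 to 2.20, adjusted exact p = 1), with Hsp27 (signal 531) and DnaJ-60 (380) the strongest. Notch pathway and proneural genes also had 11 of 29 (odds ratio 1.04, adjusted exact p = 1), with H (431) and E(spl)m3-HLH (388) the strongest. Neuronal and synaptic genes had 7 of 32 (odds ratio 0.474, interval 0.205 to 1.10, adjusted exact p = 0.106), with Rop (707) and elav (477) the strongest. The neuronal list passed the threshold under the support filter without replicate 3 (Fisher's exact test, odds ratio 0.302, adjusted p = 0.0263).

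**Figure D2:**
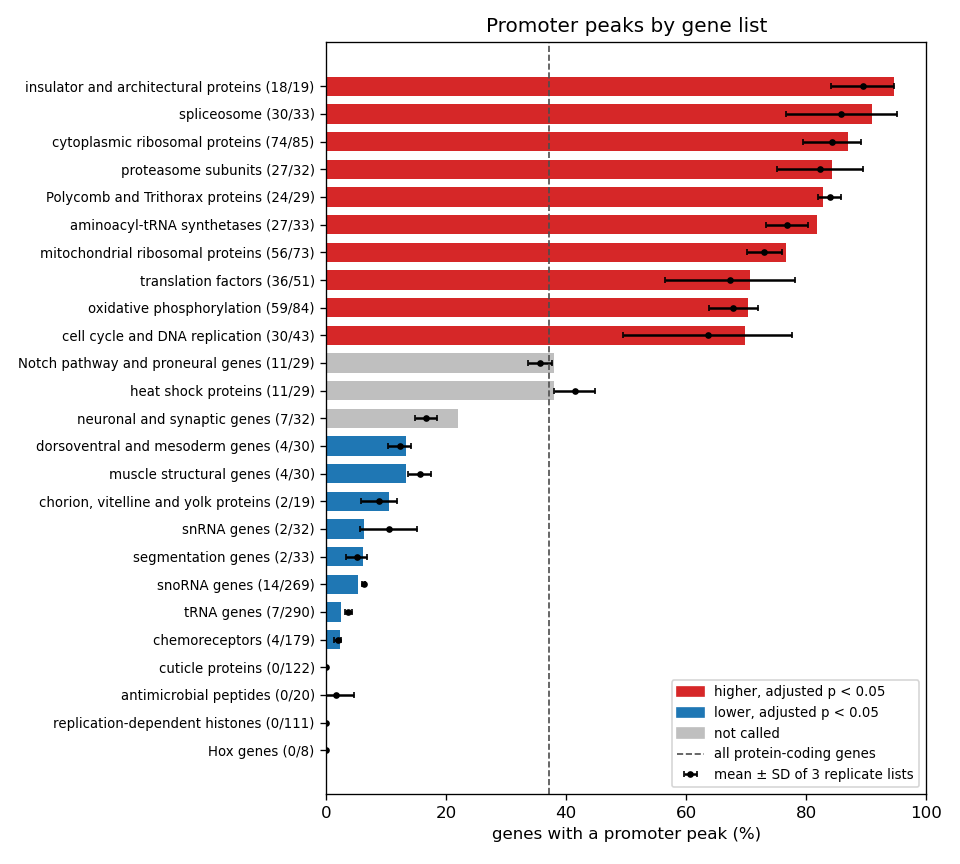
Share of genes with a promoter peak (x axis, %) in 25 gene lists (y axis, with genes that have a peak and genes in the list); bars show the thresholded peaks, points and error bars the mean ± SD of the 3 replicate lists, and the dashed line all protein-coding genes at 37.1%. The 10 lists above the line at adjusted p under 0.05 run from 69.8% to 94.7%, and the 12 below it from 0% to 13.3%.

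Genes that share a start region with a neighbour on the other strand had peaks far more often. A promoter peak was found at 3255 of 4913 genes with such a TSS upstream within 1000 bp, 66.3%, and at 1924 of 9055 other genes, 21.2% (odds ratio 7.28, interval 6.73 to 7.86, Fisher's exact p below 1e-300). A single peak can be counted for both genes of such a pair, so these genes are not independent. The interval and the p-value treat them as independent and overstate the certainty. If a divergent gene had 2 independent chances at the share of the other genes, 37.98% would have a peak. Among genes without a divergent neighbour, an alternative chosen after seeing the data, 11 of 21 testable lists passed against 22 of 25. The spliceosome, tRNA, small nuclear RNA and small nucleolar RNA lists were not testable there. All of them passed among all genes, so the 2 counts do not cover the same lists. Calls were lost there for the synthetases (5 of 10, odds ratio 3.71, Fisher's exact test, adjusted p = 0.0646), muscle genes (1 of 24, odds ratio 0.161, 0.0646), segmentation genes (2 of 32, odds ratio 0.246, 0.0670) and dorsoventral genes (2 of 27, odds ratio 0.296, 0.120), and for Hox genes (0 of 8, 0.252), the chorion list (0 of 15, 0.0689) and antimicrobial peptides (0 of 16, 0.0560). The synthetases had fewer genes there, 10 of 33, but Hox genes kept all 8 members and segmentation genes 32 of 33. The genes they were compared with also changed. For segmentation genes, 21.3% of the other genes had a peak there against 37.2% among all genes, and the odds ratio was 0.246 against 0.109.

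Promoters with a peak carried a different set of core elements. The DNA replication-related element (DRE) was found at the most upstream TSS of 24.5% of the 5179 genes with a promoter peak and 6.25% of the 8789 without (odds ratio 4.88, interval 4.39 to 5.43, adjusted exact p = 3.33e-203). Motif 1 was at 8.94% against 0.876% (odds ratio 11.1, interval 8.70 to 14.2, adjusted exact p = 2.99e-125), Motif 7 at 14.1% against 2.89% (odds ratio 5.51), Motif 6 at 3.34% against 0.569% (odds ratio 6.04) and the core promoter E-box at 5.10% against 1.79% (odds ratio 2.95). The TATA box went the other way, with 4.11% against 14.8% (odds ratio 0.247, adjusted exact p = 7.31e-97), as did the initiator, with 14.5% against 32.1% (odds ratio 0.359), and the downstream promoter element, with 3.44% against 4.88% (odds ratio 0.694, adjusted p = 4.9e-05). The MTE, a downstream core element, was found at 11 and 17 of these TSSs and did not differ (adjusted exact p = 0.846). Among the stronger 2779 peaks the calls held with odds ratios nearer 1 for the DRE (3.02), Motif 1 (4.78), Motif 6 (2.80) and the E-box (1.90), and from 60 bp upstream to 40 bp downstream that of the TATA box was 0.143. Short patterns match by chance, so these shares count sequence matches, not occupied sites.

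**Figure D3:**
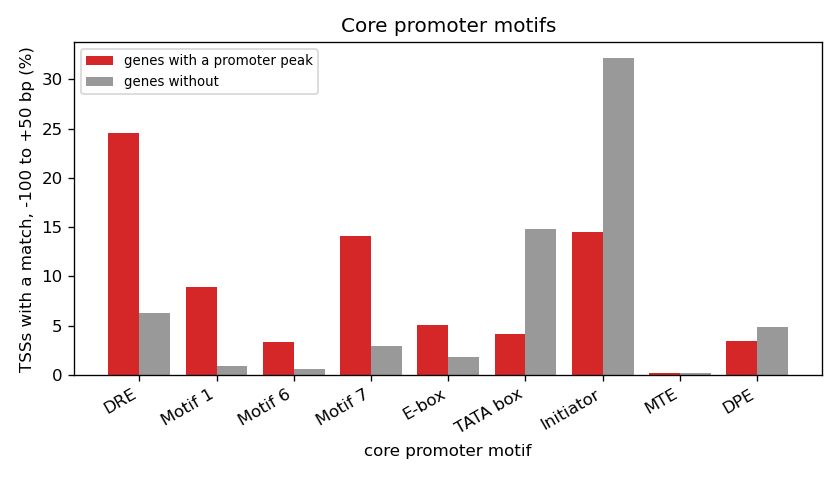
Share of protein-coding genes whose most upstream TSS has a match from 100 bp upstream to 50 bp downstream (y axis, %) for 9 core promoter motifs (x axis), in genes with and without a promoter peak. DRE matches stand at 24.5% against 6.25% and initiator matches at 14.5% against 32.1%.

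Over all peaks the same elements were more frequent at summits than in flanks, while at peaks outside promoters none of them passed the test, some with few matches. Motif 1 was within 100 bp of 5.49% of summits and in 0.198% of flanking windows (odds ratio 27.7, exact McNemar test, adjusted p = 9.22e-75), and the DRE in 12.95% against 2.68% (odds ratio 5.36, adjusted p = 7.46e-94). Motif 7 (odds ratio 5.48), Motif 6 (6.92), the core E-box (4.45), the paired CGATA sequence bound by BEAF-32 (8.60) and the shorter CAGCTG (1.40) were also more frequent at summits. The GAGA element (2.64% against 3.71%, odds ratio 0.699) and the Zelda site (0.954% against 1.67%, odds ratio 0.570) were less frequent at summits. The Pho site (odds ratio 1.16, adjusted exact p = 0.0631), the CTCF core (1.09, adjusted p = 0.344) and the Su(Hw) core (1.6, adjusted p = 0.453) did not pass, nor did the TATA box, initiator, MTE, downstream element, GATA and GT repeat. The Pho site passed at promoter peaks (odds ratio 1.32, exact McNemar adjusted p = 0.000739). At the 1026 peaks outside promoters none of the 7 motifs more frequent at summits passed, with odds ratios of 1.18 for the DRE (exact McNemar adjusted p = 0.905), 1.23 for Motif 7 (0.905), 1.00 for Motif 6 (1) and 0.714 for CAGCTG (0.202). The core E-box (5 summits and 1 flank), Motif 1 (2 and 0) and the paired CGATA sequence (1 and 0) were too rare there for their enrichment to be tested well, and among the stronger 2779 peaks odds ratios were 12 for Motif 6, 24 for the paired CGATA sequence and 0.339 for Zelda. The GAGA odds ratio was 0.443 within 50 bp, and its call was lost at promoter peaks (adjusted exact p = 0.866) and among the stronger 2779 peaks (0.395).

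Examples chosen as the highest-ranked promoter peaks with a match were TATCGATA at 9426960 to 9426967 on 3L, 71 bp from the summit at Shc, and CAGTGTGACCG at 10200988 to 10200998 on 2L, 39 bp from the summit at RpL7, which reads as Motif 1 on the other strand. Of 2080 6-mers, 524 were more frequent and 807 less frequent at summits. The highest odds ratios belonged to CGATAG (3.90), ACACTG (3.53), TATCGA (3.47), ATCGAT (2.90) and GTCACA (2.88), followed by AGTGTG, GGTCAC, AAAATA, CGATAC and GTGTGA. ATCGAT is part of the DRE consensus, and ACACTG and GTCACA of Motif 1. Summits had 39.8% G and C bases against 44.3% in the flanks, and 6-mer counts include that difference.

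The tagged gene itself had a promoter peak, at a start region that it shares with a neighbour. CG4617 (FBgn0029936) lies on the minus strand of X from 7102555 to 7104491, and the summit at 7104512 was 21 bp from its TSS, with signal 289 and rank 1569 of 5558. The neighbouring gene CG8300 starts at 7104885 on the plus strand, also within 500 bp of this summit. The peak is therefore counted for both genes and cannot be assigned to CG4617 alone. The 61 bp around it, 7104482 to 7104542, read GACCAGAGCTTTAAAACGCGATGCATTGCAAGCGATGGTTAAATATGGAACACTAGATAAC. The strongest region there ranked 1691 in replicate 1, 938 in replicate 2 and 1987 in replicate 3. A stronger peak, with signal 457 and rank 403, lay 737 bp from the gene at 7101818, inside the neighbouring gene CG4615 and 482 bp from that gene's TSS. Within 5 kb of CG4617 there were 3 thresholded peaks and within 20 kb there were 9. Of those 9, 5 lay in or just upstream of Sxl, the switch gene of sex determination, and 1 was 70 bp from the TSS of fz4, a Wnt receptor gene. Sxl, CG4615, CG8300 and fz4 were named after their values were seen.

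**Figure D4:**
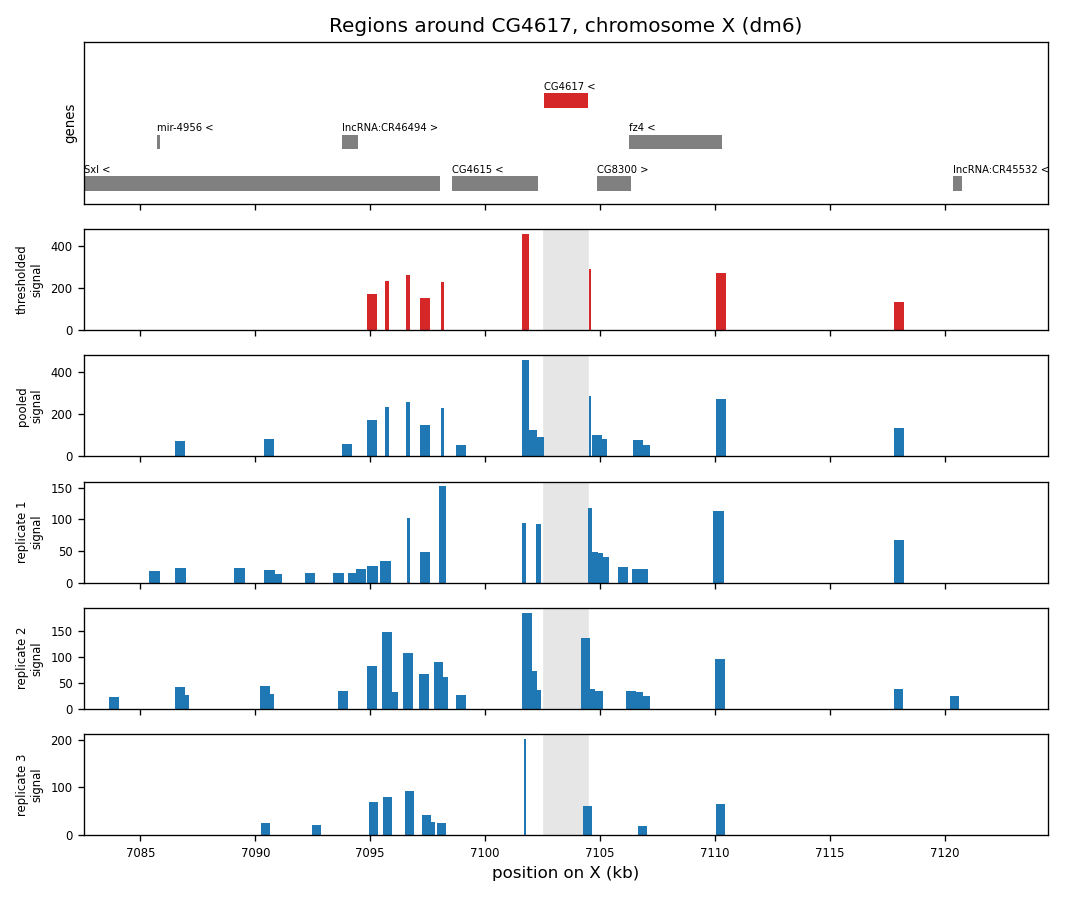
Regions within 20 kb of CG4617 on X in dm6 (x axis, kb), with genes on top (arrowheads give the strand) and below them the signal (y axis, authors' units) of each region in the thresholded, pooled and replicate lists; the grey band is CG4617. The thresholded list has 9 peaks there, the strongest, with signal 457, beside CG4617.

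The same data mapped to the older build dm3 gave 5201 thresholded peaks, against 5558 in dm6, with highest signals of 2033 and 2038. Replicate 1 had 30000 regions in both builds, replicate 2 had 15551 in dm3 and replicate 3 had 13480.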

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

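These counts were made only after the data were seen. In the dm3 lists, 28 thresholded peaks (0.538% of 5201) lay on sequences that dm3 names separately as heterochromatic. They were spread over 3LHet (10 peaks), 2RHet (8), 3RHet (5), 2LHet (3) and XHet (2), and the strongest ranked 629. They are given because where peaks lie was compared in dm6 only. Coordinates were not converted between builds, so which dm6 peaks match them is unknown, and whether they are more than chance was not tested. The replicate lists held 96, 78 and 199 regions on heterochromatic or unplaced sequences, 0.32%, 0.502% and 1.48% of each list.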

How the results depend on the processing

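Of 385 values recomputed under alternatives, 322 stayed the same. They kept direction and side of the threshold or, for counts and values without a test, stayed within a set margin of the main value. Another 29 lost the call, 6 gained one, 7 counts or values without a test moved past that margin and 21 changed direction. The cause of the changes was not tested. The peak count was 3410 when all 3 replicates had to hold the summit among their strongest regions, and 4929 with overlapping peaks merged, which was chosen after seeing the data. The signal correlation ranged from 0.406 to 0.611 when each replicate was left out. Arms past the threshold numbered 4 with sequence length as reference and 1 in the stronger 2779 peaks, against 2. Gene lists past the threshold numbered 11 of 21 testable ones among genes without a divergent neighbour, also chosen after seeing the data, against 22 of 25. The spliceosome, tRNA, small nuclear RNA and small nucleolar RNA lists are in the second count only. Motifs past the threshold numbered 2 at the 1026 peaks outside promoters, GAGA (odds ratio 0.304) and the GT repeat (0.48), both less frequent at summits, against 9 with 7 of them more frequent. CG4617 had 9 peaks within 20 kb against 3. The 5' UTR share was 39.2% with gene parts before the promoter. Arm ratios that changed side were 2L 1.07 and 2R 1.09 with sequence length, and 2R 1.01 in the stronger peaks and 1.03 in promoter peaks. The Notch list odds ratio was 0.424 within 250 bp, 0.678 in the stronger peaks and 0.963 with 1 TSS per gene, and ranged from 0.952 to 1.15 with replicates left out under the support filter; the heat shock list had 0.849 and the MTE 0.707 in the stronger peaks. At summits the TATA box had odds ratios of 0.987 within 50 bp, 0.980 in the stronger peaks and 0.925 in promoter peaks, and the GT repeat 1.07 in promoter peaks. Outside promoters odds ratios were 1.00 for Motif 6, 0.5 for the MTE, 1.23 for Zelda, 0.656 for Pho, 0.714 for CAGCTG and 1.32 for GATA. Apart from the 5' UTR share, Motif 6, Zelda, CAGCTG and both arms by length, each of these changes of direction lay between values that missed the threshold. Reads per library are unknown, so no value could be weighed by depth.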

Other observations

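The tests in this part were chosen only after the main results were seen. Those on 6-mers, 8-mers, the regions around CG4617 and the 6 developmental lists came after part of the values they rest on had been seen. The comparison of DRE shares came after both shares had been seen. Peaks outside promoters numbered 1026, of which 496 lay over 2000 bp from any annotated TSS and 74 within 500 bp of a non-coding gene's TSS. Dorsoventral and mesoderm genes were the nearest gene to 21 of these peaks, 2.05% against 0.553% from shifts (3.70 times, permutation adjusted p = 0.024 over 6 developmental lists), spread over 12 of the 30 genes. The gene ush accounted for 7 of them. This gene was already known to hold the third-strongest peak when the lists were picked, though that peak is not among the 7, the strongest of which had signal 263. Without ush, 14 peaks remained, 2.65 times the chance share, and the call was lost (permutation p = 0.026, adjusted p = 0.156 over the 6 lists). Mef2 (signal 284), dpp (242), sog (225) and bin (209), named after their values were seen, also had one. Hox genes (4 peaks, 1.32 times chance, adjusted p = 0.637), segmentation genes (7 peaks, 1.14 times, 0.637), Notch genes (3 peaks, 1.29 times, 0.637), neuronal genes (3 peaks, 0.509 times, 0.637) and muscle genes (1 peak, 0.226 times, 0.228) did not pass the same permutation test.

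At peaks outside promoters, 10 6-mers picked on 572 such peaks on 2L, 2R and X were tested on 454 on 3L, 3R and 4, where 7 passed, although leading 6-mers and 8-mers had been seen on all arms before, so these arms were not untouched data. ACACTG had odds ratios of 4.51 there and 3.78 at the 2086 promoter peaks of those arms, which did not differ detectably (Fisher's exact test, adjusted p = 0.736). This 6-mer is part of Motif 1, but the whole motif was at only 2 of all 1026 summits outside promoters. ACACTG at these peaks therefore need not stand for Motif 1. More enriched outside promoters were 4 of the 10 6-mers, AGTGTA (3.67 against 1.63, adjusted exact p = 0.00543), ACTGAG (3.96 against 1.09, 0.000481), CTGTAC (2.45 against 0.806, 0.00379) and CAGTGG (1.77 against 0.825, 0.00543), and 2 of 5 8-mers, CACTGAGA (32 summits and 0 flanks against 20 and 7, 0.00781) and CACTGTAC (16 and 2 against 17 and 15, 0.0332). G and C content alone is argued against by a median percentile of 98.4 among 6-mers with as many G and C bases. CATAGG, ACAGTA, TACCTA and CATCTA lay lower, at 88.6, 71.3, 77.8 and 92.3. ACACTG, ACAGTG and CAGTGG overlap in sequence, so the 10 are not separate cases, and other features of base composition were not tested. A DRE was at 2.53% of these summits (interval 1.74 to 3.69), less often than the 15.3% at promoter peaks. Both shares had been seen before a bound was set, and most promoter peaks also lack a DRE. Promoters that the annotation lacks therefore cannot be told apart. No biological explanation was tested.

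Promoter peaks favoured lists of genes that most cells use. That a promoter shared by 2 genes has more chances of a peak is argued against as the whole reason for these lists, since 8 of the 9 testable higher lists stayed past the threshold among genes without a divergent neighbour, for example 28 of 33 cytoplasmic ribosomal protein genes. The spliceosome list was not testable there, as too few of its genes lacked such a neighbour. For that list shared promoters cannot be told apart. Signal that follows transcription could also play a part. Cytoplasmic ribosomal protein genes, known for strong transcription, had a median signal of 236 against 254 at other genes with a promoter peak, a ratio of 0.930 within the spread (permutation p = 0.247). By the bound set before this value was seen, a median at or below that of other genes would have counted against this cause. That bound did not ask for a permutation p. As the difference lay within the spread, the bound was not applied, and this cause cannot be told apart. The embryos were whole and of mixed ages, so peaks at genes used in few cells or stages could be missed, which was not tested. Lists from a ChIP of GFP alone or of an untagged line were not analysed here, and no biological explanation was tested.

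CG4617 had 3 thresholded peaks within 5 kb against a median of 1 over protein-coding genes (percentile 77.5), 9 within 20 kb against 3 (percentile 93.7), and 10 pooled regions within 5 kb against 3 (percentile 95.3). Extra copies of the tagged gene could raise read depth there. The counts lay at percentiles 82.9, 98.5 and 83.5 in replicates 1, 2 and 3, each below the bound set for this cause. How much extra copies would change the number of listed regions is unknown, as is whether the control carries them. Region counts therefore cannot decide on extra copies. A crowding of start sites cannot be told apart: among 2117 genes with 5 start sites in the window, the pooled count lay at percentile 96.6 and the replicate counts at 85.7, 99.1 and 84.6. By the bound first set, a pooled percentile of 95 or more, crowding would have been excluded; that bound was changed after 96.6 was seen to require all 3 replicates above it, since replicates 1 and 3 lay below. The region counts themselves had been seen before either bound was set, and no biological explanation was tested.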
